A study of Mus musculus with 24 samples.

How the data were processed

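RNA was sequenced from brain and liver of male mice of a leptin receptor model that drank water, sucrose or brazzein, a sweet-tasting protein, with a treatment entry of 16 weeks in the labels. The 24 libraries make 2 tissues, 2 genotypes (db/db and db/+), 3 drinks and 2 replicates of each combination. Tissue, genotype, drink and replicate were taken from the sample titles. The separate genotype entry of the labels contradicts the title for 12 of the 24 samples and was not used. Per the labels' protocols, RNA was extracted with TRIzol, enriched for poly(A) RNA and made into libraries with a NEBNext Ultra II RNA kit. The kit named is not a directional one, so overlapping and antisense genes were not told apart. Per the submitters' processing notes, reads were handled with bcl2fastq and referred to the genome build GRCm39. The aligner, the counting tool and the annotation are not given in the sources used here, and neither is the brain region.

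The deposited per-sample files hold 1 whole number for each of 55797 gene names, and these values are expected counts, that is, counts estimated from coverage and not scaled for library size. The deposited series table holds the coverage signal of each gene in each sample and, in its second set of columns, FPKM values. Each FPKM value is the coverage divided by 1 factor per sample, between 6.09 and 8.37, and between 99.8% and 99.9% of genes lay within 1% of that factor. The counts were used for all tests and the coverage and FPKM only for checks of the files. For the db/+ brazzein livers, the counts of replicate 1 matched the coverage column of replicate 2 and the reverse, an exchange within 1 group that changes no group. Gene names were used as the files give them, and no coordinates are printed because the reference annotation at hand is of another build than GRCm39.

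Total estimated counts per library ran from 58287665 to 77772849 in brain and from 60384569 to 79385804 in liver. Genes above 0 numbered 28711 to 30180 per brain library and 22169 to 24115 per liver library. Because the counts are estimates, no counting interval was computed, and a gene at 0 is described as listed at 0.

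Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group, quasi-likelihood tests), with 1 fit of 6 groups per tissue, each group holding 2 libraries. After the filter, 19352 liver genes and 23653 brain genes were tested. Comparisons were genotype averaged over drinks, genotype on each drink, each pair of drinks within each genotype, and the interaction of genotype with drink. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. P-values measure the spread between samples, and nothing in the labels says whether replicates are separate animals. Values are in CPM (counts scaled to the library total) with TMM-scaled library sizes, given as mean ± SD over libraries, and fold changes are log2 with their standard error (SE).

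The design, the alternatives, the gene lists (28 for liver, 35 for brain) and the rule for named genes were set before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The rule for named genes took a fixed panel for each tissue with Lepr in both. For a comparison with 20 or more calls it added up to 8 higher and 8 lower genes with official symbols, a mean of at least 1 CPM, no overlap between the sides and the greatest fold, and up to 4 members per list with any call. For fewer calls it took up to 10 genes by smallest p. Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, a replicate block and leaving out each library. Another 3 were added after seeing the data: leaving out genes listed near 0, leaving out 2 liver libraries, and leaving out 3 brain libraries.

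The steps were tested on simulated counts with known changes, 100 genes at each fold in each comparison. The real liver genotype comparison called 2937 genes. Adjustment over all genes is stricter when fewer genes change, so the percentages below are not the recovery in that comparison. For the liver genotype comparison, with 18755 genes in the simulated step, 14% of 2-fold and 70% of 4-fold changes were recovered, and 9 of 94 calls were of unchanged genes. For brazzein against sucrose in db/db liver, the same step recovered 0% and 3%. For the brain genotype comparison (23193 genes), it recovered 77% and 94%, with 19 of 246 calls of unchanged genes. For brazzein against sucrose in db/db brain it recovered 26% and 74%.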

Results

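Gene expression was measured by RNA sequencing in 12 brain and 12 liver libraries of male mice. In each tissue, 6 libraries came from db/db mice, which carry a defective leptin receptor, and 6 from db/+ mice, which carry a functional copy. Within each genotype, 2 libraries came from mice on water, 2 on sucrose and 2 on brazzein. The series set out to examine how brazzein and sucrose intake affect brain and liver in this model. Totals per library ran from 58287665 to 77772849 estimated counts in brain and from 60384569 to 79385804 in liver.

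Lepr, the gene altered in this model, was examined first. In liver, the db/+ libraries held 2.43 and 6.65 CPM on water, 14.0 and 18.9 on sucrose, and 1.90 and 2.77 on brazzein. The db/db libraries held 1.34 and 0.690 on water, 1.56 and 2.50 on sucrose, and 1.45 and 1.63 on brazzein. Averaged over drinks, Lepr fell by 1.93 on the log2 scale (SE 0.32, edgeR quasi-likelihood adjusted p = 0.00788). In brain, the db/+ libraries held 3.58 and 3.37 CPM on water, 3.87 and 3.31 on sucrose, and 3.13 and 3.43 on brazzein, and the db/db libraries held 2.32 and 2.77, 2.77 and 2, and 2.60 and 2.40 (log2 difference -0.48, SE 0.11, edgeR adjusted p = 0.158). The count per gene pools the long and short receptor forms, so these values do not check the mutation.

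Genes of fat synthesis and storage were higher in db/db than in db/+ liver, the comparison that asks what the loss of leptin signalling does to this organ. Fasn, the fatty acid synthase, rose from 43.5 ± 9.33 to 239 ± 50.6 CPM (SD, n = 6 each, log2 2.47, SE 0.16). Thrsp, a regulator of lipogenesis, rose from 21.5 ± 23.2 to 525 ± 169 CPM (log2 4.94, SE 0.34), and Cidec, a protein of lipid droplets, from 42.4 ± 33.4 to 236 ± 29.6 CPM (log2 2.81, SE 0.25). Of 21 genes of de novo lipogenesis, 14 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 of 1.24. Of 28 genes of glycolysis and fructose use, 17 rose and 0 fell (18 and 2 adjusted over the list alone), among them Pklr (log2 2.73, SE 0.29) and Khk (1.34, SE 0.15). Of 29 genes of lipid droplets and lipid uptake, 10 rose and 0 fell (15 and 1 adjusted over the list alone), including Mogat1 (log2 3.37, SE 0.21) and the fatty acid transporter Cd36 (1.66, SE 0.18). Camera passed these 3 lists (adjusted p = 2.7e-12, 1.57e-09 and 2.18e-06), with an adjusted p of 0.107 for each with an estimated correlation. Of 24 cholesterol synthesis genes, 9 rose (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.69e-07, adjusted p = 0.329 with an estimated correlation). Of 38 genes of fatty acid oxidation and ketogenesis, 9 fell and 2 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.581 with an estimated correlation), with Cyp4a14 at 2273 ± 668 against 5716 ± 1203 CPM.

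Other panel genes of liver metabolism went both ways or did not pass in edgeR. Scd1, which desaturates fatty acids, rose (log2 2.14, SE 0.36), as did Pparg (1.26, SE 0.28) and Cpt1a (1.00, SE 0.25). Cidea averaged 154 ± 52.2 CPM in db/db and 0.218 ± 0.204 in db/+. Acaca, the acetyl-CoA carboxylase of fat synthesis, passed at an edgeR adjusted p of 0.0465, but it was at 17.0, 21.7 and 34.3 CPM in 3 db/db libraries (both on sucrose and replicate 1 on water) and at 0.0346 to 0.590 CPM in the other 9, all 6 db/+ libraries among them, so the call rests on those 3. The edgeR adjusted p was 0.0502 for Plin2, 0.0666 for Srebf1, 0.0746 for Cyp8b1, 0.149 for Fgf21, 0.169 for Cyp7a1, 0.212 for Pck1 and 0.253 for G6pc. Apoa4, an apolipoprotein, rose from 1596 ± 2320 to 10460 ± 3758 CPM (log2 3.82, SE 0.38).

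Genes whose liver expression differs between the sexes, and genes downstream of growth hormone, also separated the genotypes. Of 31 male-biased genes, 27 fell and 0 rose (30 and 0 adjusted over the list alone, median log2 -3.71), including Serpina1e at 23.1 ± 7.25 against 2199 ± 1373 CPM and the complement gene C8b at 26.01 ± 7.21 against 173 ± 52.0 CPM. Of 30 female-biased genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), including Cyp2b13 (135 ± 105 against 0.311 ± 0.249 CPM) and Sult3a1, which was listed at 0 in all 6 db/+ libraries and at 1.43 ± 0.737 CPM in db/db. Of 16 genes of the growth hormone and IGF axis, 5 fell and 0 rose (7 and 0 adjusted over the list alone). Igfbp2, a binding protein for insulin-like growth factors, averaged 14.1 ± 8.45 against 944 ± 188 CPM (log2 -6.08, SE 0.46), and Igf1 240 ± 64.1 against 592 ± 144 CPM (log2 -1.29, SE 0.19). Camera gave the male-biased list an adjusted p of 1.55e-28 (adjusted p = 0.110 with an estimated correlation), the female-biased list 3.31e-05 (adjusted p = 0.251 with an estimated correlation) and the growth hormone list 0.00406 (adjusted p = 0.107 with an estimated correlation). Many Mup genes, which encode urinary pheromone carriers, were among the lower genes (Mup7 at 21.3 ± 25.1 against 3884 ± 3595 CPM). Mup, Cyp2b and Sult genes are near-identical copies, so the split of reads within each family is uncertain.

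**Figure D1:**
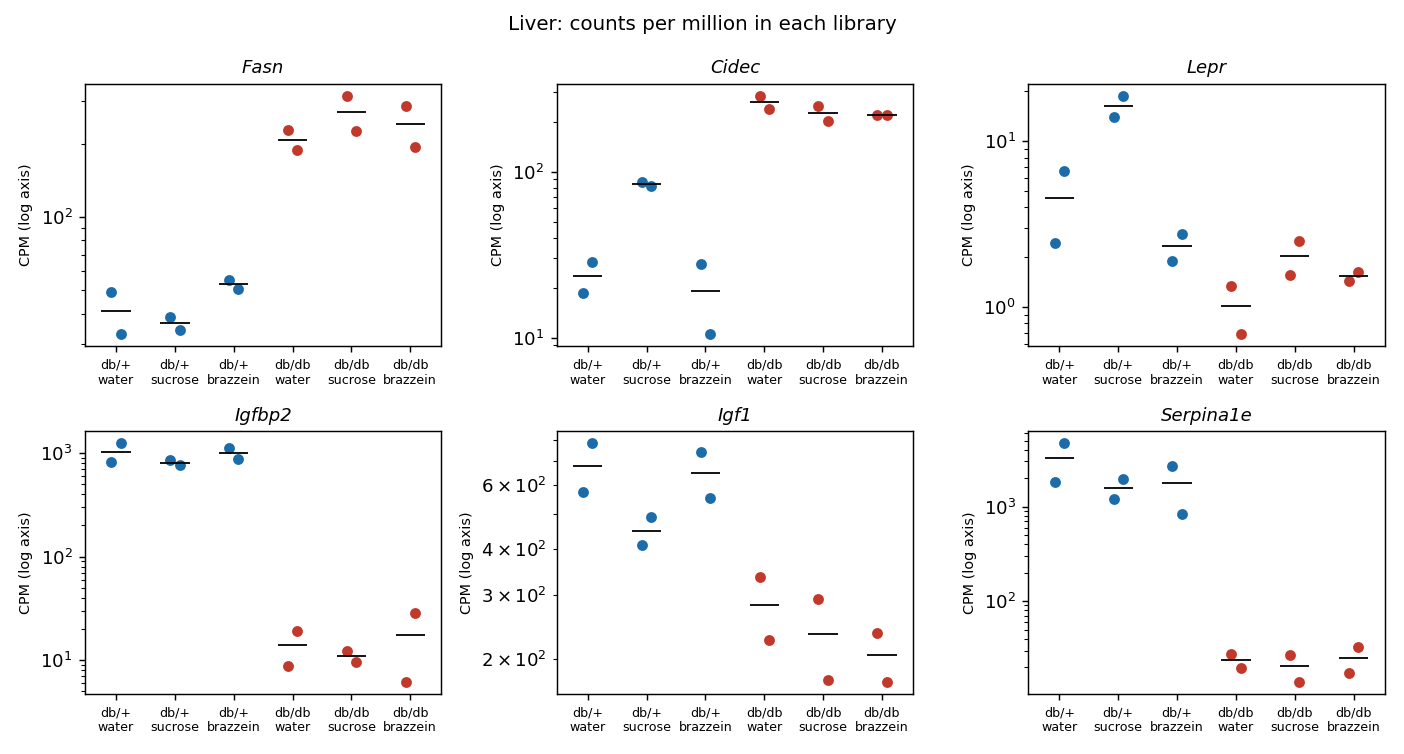
Liver CPM (log axis) of 6 genes in each genotype and drink, with 1 point per library and a line at the mean of 2 libraries. Fasn and Cidec lie higher in db/db libraries, and Igfbp2, Igf1 and Serpina1e lie lower.

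Immune, matrix and cell cycle genes moved with genotype in liver as well. Of 36 cell cycle genes, 18 rose (28 adjusted over the list alone), including the proliferation marker Mki67 at 5.43 ± 2.58 against 1.01 ± 0.387 CPM. Of 31 macrophage and Kupffer cell genes, 12 rose (16 adjusted over the list alone), including Gpnmb (6.35 ± 3.31 against 0.167 ± 0.115 CPM) and Trem2 (3.13 ± 1.17 against 0.340 ± 0.172 CPM), and of 41 genes of matrix and stellate cells 13 rose and 2 fell (16 and 2 adjusted over the list alone), with the collagen gene Col1a1 at 7.35 ± 1.72 against 2.78 ± 0.777 CPM. Of 29 acute phase genes, 12 rose and 4 fell (15 and 6 adjusted over the list alone), with Saa1 at 72.6 ± 50.7 against 15.5 ± 10.1 CPM and Lcn2 at 134 ± 64.0 against 8.48 ± 11.7 CPM, while Serpina3k fell by 1.55 on the log2 scale. Of 25 unfolded protein response genes, 8 fell and 1 rose (13 and 4 adjusted over the list alone), such as the chaperones Hyou1 (log2 -1.36, SE 0.23) and Calr (-0.70, SE 0.14). Camera adjusted p-values were 4.79e-13 for cell cycle (adjusted p = 0.181 with an estimated correlation), 1.88e-08 for macrophages (adjusted p = 0.331 with an estimated correlation) and 0.00184 for matrix (adjusted p = 0.532 with an estimated correlation). They were 0.0116 for acute phase (adjusted p = 0.532 with an estimated correlation) and 0.0229 for the unfolded protein response (adjusted p = 0.570 with an estimated correlation). Camera also passed chemokines and cytokines (6 of 30 genes higher and 3 lower, 9 and 3 adjusted over the list alone), neutrophils (2 of 11 higher, 4 adjusted over the list alone) and erythroid cells (5 of 10 higher, 5 adjusted over the list alone). Their camera adjusted p-values were 0.000838, 0.00118 and 0.0104, and their adjusted p-values with an estimated correlation 0.462, 0.251 and 0.532. Markers of blood moved with genotype in these livers, with Hba-a1 at 529 ± 238 against 244 ± 43.6 CPM. The share of counts from mitochondrial ribosomal RNA moved with it too, at 0.263% to 0.336% in db/db and 0.578% to 1.29% in db/+ livers.

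In all, 1531 liver genes were higher and 1406 lower in db/db, by edgeR quasi-likelihood tests of 19352 genes. Of those tested, 6109 had an unadjusted p under 0.05 where chance gives 968, and DESeq2 called 4848. The other 12 liver lists did not pass camera for genotype (adjusted p 0.0694 to 0.747). These were bile acid synthesis, gluconeogenesis, lipoproteins, oxidative phosphorylation, xenobiotic metabolism, interferon response, lymphocytes, endothelial cells, cholangiocytes, circadian clock, heat shock genes, and adipocyte and pancreas markers. Of the 2937 genes called, 155 had a median of at least 100 counts and a library under 0.1 of it. The total of 2937 depended on the libraries. It was 1934 without db/+ sucrose replicate 2, 1818 without db/+ water replicate 2, 1715 and 1407 without db/db sucrose replicate 1 or 2, and 1918 and 1417 without db/db water replicate 1 or 2.

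On each drink taken alone, the genotypes differed in fewer liver genes, and Igfbp2 and Serpina1e were lower in db/db on each. Igfbp2 averaged 13.9 ± 7.37 against 1026 ± 299 CPM on water, 11 ± 1.83 against 809 ± 70.9 on sucrose, and 17.5 ± 16.0 against 996 ± 165 on brazzein (SD, n = 2 each). Cidec passed on water (263 ± 33.9 against 23.4 ± 7.02 CPM) and brazzein (219 ± 1.10 against 19.2 ± 12.3 CPM), and held 226 ± 31.99 against 84.7 ± 3.25 CPM on sucrose (edgeR adjusted p = 0.145), with an interaction adjusted p of 0.599. By edgeR, 188 genes were higher and 105 lower on water, 91 and 77 on sucrose, and 179 and 126 on brazzein, with DESeq2 counts of 2132, 1590 and 1912. Of these calls, 36, 29 and 65 rested on genes with a median of at least 100 counts and a library under 0.1 of it. Leaving out any of several libraries moved these totals by more than 1.5 times, over 14 to 606 on water (lowest without db/db water replicate 2, highest without db/+ brazzein replicate 2), 19 to 438 on sucrose (without db/+ sucrose replicate 1 and db/+ brazzein replicate 2) and 131 to 389 on brazzein (lowest without db/db brazzein replicate 2).

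The central drink comparison asks how brazzein differs from sucrose in db/db liver. Genes of oxidative phosphorylation, which encode the respiratory chain, were higher on brazzein, with a median log2 of 0.70 over 43 genes. Over all genes 0 of the 43 passed, and 36 did adjusted over the list alone, such as Ndufa7 (187 and 213 against 113 and 104 CPM, log2 0.88, SE 0.13, edgeR adjusted p = 0.0509). Camera passed the list (adjusted p = 3.55e-28, adjusted p = 0.0335 with an estimated correlation). The genes of cytosolic ribosomal proteins, a group chosen after the data were seen, had a median log2 of 0.62 in the same comparison, with 85 of 88 above 0. Short transcripts were on the higher side in general: transcript length and log2 had a Spearman correlation of -0.52 across 6312 genes, and random lists matched to the oxidative phosphorylation genes on length and level had a median log2 of 0.52. The db/db brazzein libraries also had the lowest correlation between replicates of the liver groups (0.818, with 0.838 to 0.954 in the others). Against water in db/db liver, the oxidative phosphorylation list had a median log2 of 0.41 on brazzein (0 genes over all genes, 22 adjusted over the list alone, camera adjusted p = 3.22e-14, adjusted p = 0.192 with an estimated correlation) and -0.31 on sucrose (0 genes in either count, camera adjusted p = 2.31e-13, adjusted p = 0.217 with an estimated correlation). In these comparisons with water, the ribosomal protein genes had a median log2 of 0.42 on brazzein (85 of 88 above 0). On sucrose it was -0.18 (5 of 88 above 0). Whether the oxidative phosphorylation list responded otherwise in db/+ liver was not tested as a difference.

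**Figure D2:**
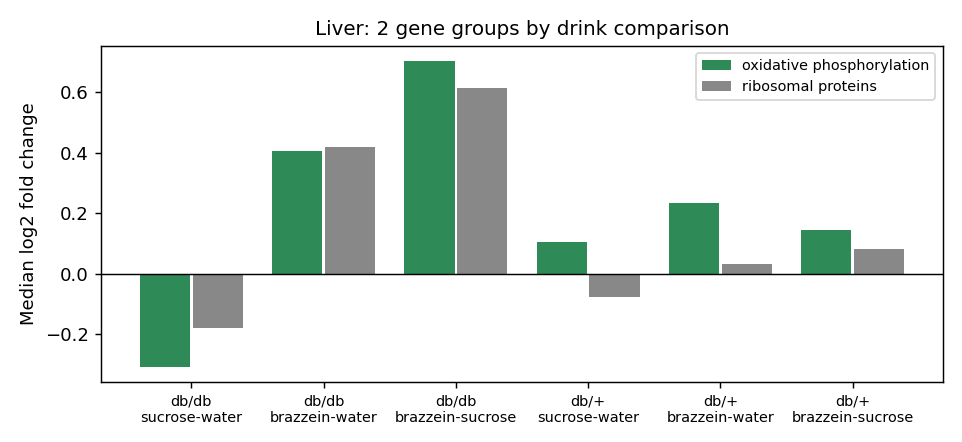
Median log2 fold change of 43 oxidative phosphorylation genes and 88 ribosomal protein genes in liver, for each pair of drinks within each genotype. In db/db, both groups lie higher on brazzein than on sucrose (0.70 and 0.62).

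Single genes that passed between brazzein and sucrose in db/db liver were few. Ugt1a2, a glucuronidation enzyme from a locus whose genes share exons, was at 168 ± 7.07 against 23.5 ± 6.70 CPM (SD, n = 2 each, log2 2.84, SE 0.38, edgeR adjusted p = 0.0432). Lamb3, a laminin chain, was at 29.5 ± 1.29 against 0.360 ± 0.0328 CPM (log2 6.35, SE 0.77, edgeR adjusted p = 0.0310), and Fau, which encodes a ribosomal protein, at 370 ± 12.9 against 210 ± 5.26 CPM (log2 0.82, SE 0.11, edgeR adjusted p = 0.0428). In all 5 genes were higher and 26 lower by edgeR, with 2848 at an unadjusted p under 0.05 where chance gives 968, and 1378 by DESeq2. Of the 31, 20 had a median of at least 100 counts and a library under 0.1 of it. Among them were Mef2d and Kbtbd2, listed at 0 in both brazzein libraries, and Ddx6 and Ufl1, listed near 0 there. Farp1, another of the lower genes, was at 7.70 and 12.9 CPM in the db/db sucrose libraries and at 0 to 0.238 in the other 10 livers. The calls of Ugt1a2, Lamb3 and Fau were lost without db/db sucrose replicate 1 (edgeR adjusted p = 0.236, 0.201 and 0.237) or without db/db sucrose replicate 2 (0.142, 0.199 and 0.199). Without db/db brazzein replicate 2 they were lost as well (0.120, 0.0652 and 0.143), and the count was 302 without db/db brazzein replicate 1, 113 without db/+ brazzein replicate 1 and 115 without db/+ brazzein replicate 2.

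**Figure D3:**
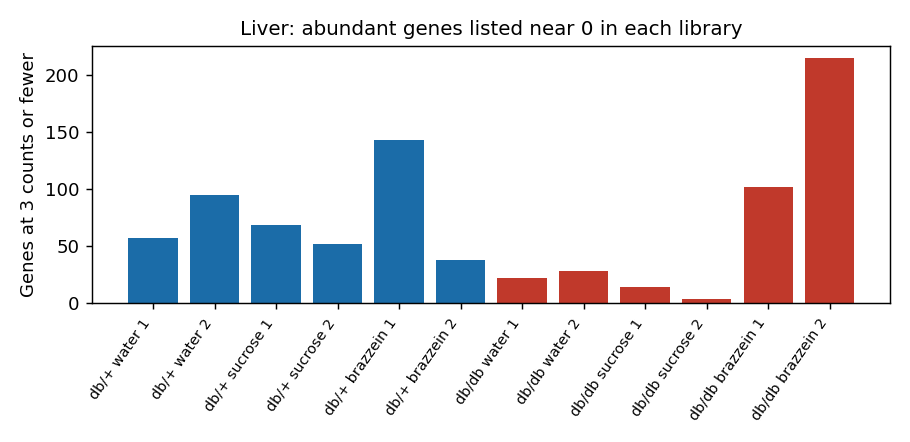
Number of liver genes at 3 estimated counts or fewer in each library (bars from 0), among 11348 genes with a median of at least 100 counts over the 12 libraries. The counts run from 4 in db/db sucrose replicate 2 to 215 in db/db brazzein replicate 2.

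Further lists in db/db liver passed camera only at the preset correlation. Between brazzein and sucrose these were fatty acid oxidation (median log2 0.31, adjusted p = 0.00558), lipid droplets (0.39, adjusted p = 0.0349) and macrophages (-0.48, adjusted p = 0.0349), each with 0 genes called over all genes or adjusted over the list alone, and each with adjusted p = 0.981 with an estimated correlation. Between brazzein and water it was male-biased genes (-0.70, adjusted p = 0.00940, and adjusted p = 0.957 with an estimated correlation). Between sucrose and water, macrophages (median log2 0.71), lymphocytes (0.66), chemokines (0.48), endothelial cells (0.35), interferon response (0.32) and matrix (0.19) were on the higher side. Erythroid cells (-0.58), male-biased (-0.85) and female-biased genes (-0.30), xenobiotic metabolism (-0.38), acute phase (-0.38), lipid droplets (-0.30) and fatty acid oxidation (-0.25) were on the lower side. Their adjusted p-values with an estimated correlation were 0.386 to 0.643, and xenobiotic metabolism alone had members called adjusted over the list alone (1 higher, 3 lower). Of the 28 lists, camera passed 14 between sucrose and water, 2 between brazzein and water and 4 between brazzein and sucrose. The 14 were 9 without db/db water replicate 2. The 2 were 6 without db/db brazzein replicate 2 or db/db water replicate 1, and 1 without db/db water replicate 2. The 4 were 2 without db/db brazzein replicate 1 or db/db sucrose replicate 2, 10 without db/db brazzein replicate 2 and 9 without db/db sucrose replicate 1.

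Against water, few db/db liver genes passed on either drink. On sucrose 1 gene passed, Gm8893, a predicted gene named after its values were seen (296 and 220 CPM against 5.83 and 7.90, log2 5.23, SE 0.27, edgeR adjusted p = 0.000832). For sucrose, 827 genes had an unadjusted p under 0.05, fewer than the 968 that chance gives, and DESeq2 called 76. On brazzein 3 genes were higher and 20 lower by edgeR (1658 at an unadjusted p under 0.05, DESeq2 561), including Wdr25 (3.29 ± 0.948 against 0.121 ± 0.0467 CPM). Of the 23, 19 had a median of at least 100 counts and a library under 0.1 of it. The brazzein count was 200 without db/db brazzein replicate 1, 63 without either db/+ brazzein replicate and 37 without either db/+ sucrose replicate. The sucrose count was 5, 9 and 12 without db/db sucrose replicate 1, db/db sucrose replicate 2 and db/db water replicate 1.

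Whether brazzein moved the db/db liver back toward db/+ relative to sucrose was examined over the genes called for genotype on water. The 188 genes that were higher in db/db had a median brazzein against sucrose log2 of 0.05 and the 105 lower genes 0.08. The difference of -0.02 was smaller than the spread over pairs of replicates (SD 0.124). With all libraries neither set passed limma's camera (adjusted p = 0.250 and 0.249). The lower set passed, on the higher side, without db/+ brazzein replicate 1 (camera adjusted p = 9.25e-05, adjusted p = 0.483 with an estimated correlation), db/+ brazzein replicate 2 (adjusted p = 0.000101 and 0.466) or db/db sucrose replicate 1 (adjusted p = 6.22e-05 and 0.195). These sets were selected on libraries of the same fit. Without 1 library the difference ran from -0.27 (without db/db sucrose replicate 1) to 0.25 (without db/db sucrose replicate 2), so its sign was not settled.

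In db/+ liver, Cyp2c70, an enzyme that makes muricholic bile acids, was at 95.9 ± 6.20 CPM on brazzein and 10.9 ± 3.14 on sucrose (SD, n = 2 each, log2 3.14, SE 0.31, edgeR adjusted p = 0.0354), with 44.4 ± 7.86 on water. Pwp2, a factor of ribosome assembly, was listed at 0 in both brazzein libraries and at 12.1 and 12.8 CPM on water and 9.75 and 10.2 on sucrose. Cdc42se2 was at 0.0173 and 0 CPM on sucrose against 8.63 and 6.58 on water, and Kbtbd2 at 11.2 and 12.6 against 0 in both. By edgeR, sucrose against water gave 1 higher and 2 lower genes (1158 at an unadjusted p under 0.05, DESeq2 225), the third being Gm26712, a predicted gene named after its values were seen. Brazzein against water gave 0 higher and 1 lower (1172, DESeq2 175) and brazzein against sucrose 3 and 1 (1693, DESeq2 440). The call of Cyp2c70 was lost without db/+ sucrose replicate 1 (edgeR adjusted p = 0.0991), either db/+ water replicate (0.0548 and 0.0608) or either db/db water replicate (0.105 each), and the count for brazzein against sucrose rose to 97 and 105 without db/+ brazzein replicate 1 or 2. Leaving out db/+ water replicate 1 gave 46 genes for sucrose against water, and leaving out any db/db sucrose or db/db water library gave 0. For brazzein against water the count was 94 without db/+ brazzein replicate 2 and 39 without db/+ brazzein replicate 1 or db/+ water replicate 1.

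In brain, few single genes separated the genotypes. Sparc, a matrix protein of astrocytes and vessels, was at 902 ± 21.7 CPM in db/db and 745 ± 52.1 in db/+ (SD, n = 6 each, log2 0.28, SE 0.02, edgeR adjusted p = 0.0379), and the complement gene C4b at 46.9 ± 2.51 against 34.6 ± 1.75 CPM (log2 0.44, SE 0.04, edgeR adjusted p = 0.0379). These 2 were the genes that rose and 0 fell, with 3275 at an unadjusted p under 0.05 where chance gives 1183, and 869 by DESeq2. With a replicate block neither Sparc nor C4b passed. The call of C4b was lost without db/+ brazzein replicate 1 (edgeR adjusted p = 0.0521), db/+ sucrose replicate 1 (0.0781), db/+ sucrose replicate 2 (0.0786) or db/db sucrose replicate 1 (0.0761), and the count ran from 1 without db/+ sucrose replicate 2 to 42 without db/db brazzein replicate 1. Feeding peptides gave values without calls: Agrp 0.855 ± 0.209 against 0.738 ± 0.120 CPM, Npy 40.7 ± 2.88 against 38.6 ± 4.06, and Pomc 1.77 ± 0.244 against 9.23 ± 10.2. The edgeR adjusted p was 0.147 for Ttr (1189 ± 63.9 against 928 ± 107.7 CPM) and 0.192 for Pomc, and between 0.350 and 0.928 for Agrp, Npy, Bdnf, Fos, Gfap, Aif1, Il1b, Mbp, Th, Tph2, Drd1, Drd2 and Socs3. Tnf was among the genes too low to be tested. On water alone, Sparc (log2 0.43, edgeR adjusted p = 0.04996) and Acot7, a thioesterase of neurons (319 ± 7.84 against 73.9 ± 23.6 CPM, log2 2.11, edgeR adjusted p = 0.0494), passed and 0 genes fell (1607 at an unadjusted p under 0.05, DESeq2 145). With RLE factors or with a replicate block that count was 0. Both calls were also lost without either library of db/+ brazzein, db/db brazzein or db/db sucrose. On sucrose and on brazzein edgeR called 0 genes (2205 and 1928 at an unadjusted p under 0.05, DESeq2 343 and 218), with up to 19 without db/db sucrose replicate 2 and up to 29 without db/db brazzein replicate 1.

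For genotype in brain, camera passed 15 gene lists at the preset correlation and 0 with an estimated correlation. Stress and glucocorticoid response genes had a median log2 of 0.35 over 28 genes (0 passed over all genes, 9 adjusted over the list alone). Examples named after their values were seen are Fkbp5 (log2 0.64, SE 0.14, edgeR adjusted p = 0.149) and the metallothionein Mt2 (0.46, SE 0.06, adjusted p = 0.0694). Reactive astrocyte genes had a median of 0.26 (3 adjusted over the list alone), meninges and fibroblasts 0.19 (4), oxidative phosphorylation 0.07 (10), choroid plexus 0.10 (1), hepatocyte markers 1.49 (1) and reactive microglia 0.07 (2). Interferon response (0.17), ependymal cells (0.11) and erythroid cells (0.57) had 0 members passing adjusted over the list alone. On the lower side were oligodendrocytes and myelin (-0.13, 7 lower and 1 higher adjusted over the list alone), microglia (-0.14, 4 lower), glutamate receptors (-0.10, 3 lower), oligodendrocyte precursors (-0.09, 0) and pituitary (-0.55, 0). Over all genes, 0 members of any of these 15 lists passed. Camera passed them with adjusted p from 6.6e-10 for the stress response to 0.0370 for ependymal cells, and their adjusted p was 0.139 to 0.573 with an estimated correlation. The other 20 lists did not pass (adjusted p 0.0630 to 0.949). They hold astrocytes, interneurons, synapses, neurotrophins, neural progenitors, dopamine and serotonin signalling, feeding neuropeptides, insulin and leptin signalling, immediate early genes, cholesterol synthesis, circadian clock, endothelial cells, heat shock, the unfolded protein response and the 5 sets of brain region markers.

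Some brain libraries stood apart, and their genes move with the genotype groups. Gh, the growth hormone gene of the pituitary, was at 311 CPM in db/+ sucrose replicate 1 and 111 in db/+ brazzein replicate 2, and at 0 to 7.57 in the others. Pomc, also a pituitary gene, was at 10.9 and 28.8 CPM in the same libraries. Pcp2, a marker of cerebellar Purkinje cells, was at 17.3 CPM in db/+ water replicate 1 and 60.7 to 72.6 in the others. Alb, the albumin gene of hepatocytes, was listed at 0 in all 6 db/+ brains and above 0 in 4 of the 6 db/db brains (0.476, 2.46, 3.78 and 4.82 CPM). On the first principal component of 2000 genes, db/db sucrose replicate 1 stood at 62.3 and the others at -27.4 to 18.5, and this library had the smallest total of estimated counts and the most genes at 3 counts or fewer (16 of 15059 genes with a median of at least 100 counts, with 3 to 14 in the others). Without it edgeR called 7 genes for genotype. Without the db/+ libraries high in Gh or low in Pcp2, edgeR called 6 genes for genotype, and neither Sparc (adjusted p = 0.119) nor C4b (adjusted p = 0.217) passed.

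**Figure D4:**
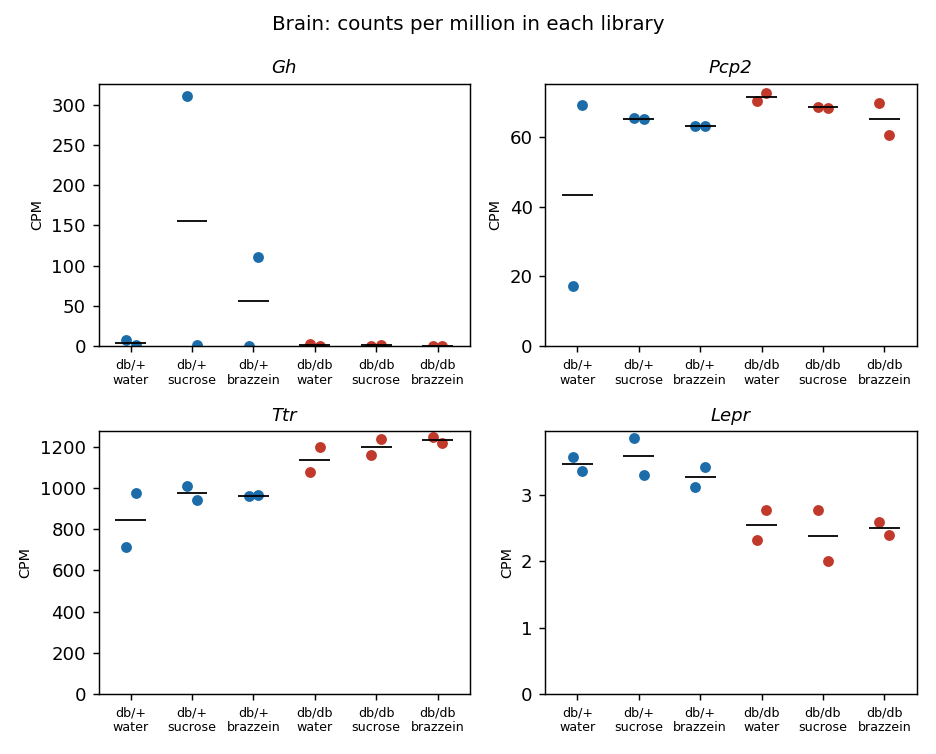
Brain CPM of Gh, Pcp2, Ttr and Lepr in each genotype and drink, with 1 point per library and a line at the mean of 2 libraries. Gh stands at 311 and 111 CPM in 2 db/+ libraries and Pcp2 at 17.3 CPM in 1.

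The drinks were compared in brain to ask whether brazzein or sucrose intake changes expression there. Between brazzein and sucrose in db/db, Zbtb34, a zinc finger gene, was at 14.5 and 12.1 CPM against 0 and 0.116, and Catsper2, known from sperm, at 0.0424 and 0.0668 against 1.87 and 2.21 (edgeR adjusted p = 0.0422 and 0.0227). These were 1 higher and 1 lower gene, with 1268 at an unadjusted p under 0.05 where chance gives 1183, and 111 by DESeq2. The count was 0 without any db/+ brazzein or db/+ water library and 18 without db/db brazzein replicate 1. Against water in db/db brain, edgeR called 0 genes on sucrose and 0 on brazzein (1704 and 1139 at an unadjusted p under 0.05, DESeq2 165 and 93), with 30 and 22 without db/db water replicate 1. Immediate early genes, which respond to neuronal activity, had a median log2 of 0.29 on sucrose and 0.42 on brazzein against water. Cholesterol synthesis genes had 0.15 and 0.08. Camera passed both lists in both comparisons (adjusted p = 0.000155 and 6.9e-05, then 7.48e-05 and 0.0460). With an estimated correlation the adjusted p was 0.977 and 0.927 for immediate early genes and 0.502 and 0.927 for cholesterol synthesis, and 0 members passed in any count. Without db/db water replicate 2, immediate early genes did not pass between sucrose and water, while cholesterol synthesis did (adjusted p = 0.0299). The brazzein against water lists were 0 without db/db water replicate 2, and 1 without any of 8 other libraries (all but db/+ brazzein replicate 1, db/db brazzein replicate 1 and db/db water replicate 1), when immediate early genes were the list left. In db/+ brain, edgeR called 0 genes for sucrose against water, 0 for brazzein against water and 0 for brazzein against sucrose (1116, 1150 and 751 at an unadjusted p under 0.05, DESeq2 82, 74 and 48), with 73 in each of the first pair without db/+ water replicate 2 and 13 in the last without db/+ brazzein replicate 1 or db/+ sucrose replicate 1. The interaction of genotype with drink gave 0 brain genes by edgeR (1290 at an unadjusted p under 0.05, DESeq2 194), and 26 without db/+ water replicate 2.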

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

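The tests of genes listed near 0 in liver were chosen only after the result was seen.

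The effect of the drinks differed between the genotypes for 12 liver genes by edgeR's interaction test (1411 genes at an unadjusted p under 0.05, DESeq2 381). With the replicate block the test called 5 genes. It called 2 without the genes listed near 0, a fit that takes such genes out of the test. Pwp2 was listed at 0 in both db/+ brazzein livers and at 9.75 to 14.8 CPM in the other 10 (adjusted p = 0.000884). Gm8893 was at 5.83 and 7.90 CPM in db/db livers on water and at 185 to 666 CPM in the others (adjusted p = 0.00369). Tent4a (0.00369), Mef2d (0.00730), Ufl1 (0.0135), Unkl (0.0135) and Ddx6 (0.0315) were near 0 in both db/db brazzein livers, with the adjusted p in brackets. Wdr25 (0.00730) was under 0.2 CPM in db/+ brazzein, db/db water and db/db sucrose livers and at 1.55 to 3.96 in the rest. Kbtbd2 (0.0135) was near 0 in db/+ water, db/+ brazzein and db/db brazzein livers, and Cdc42se2 (0.0135) in db/+ sucrose livers. Of the 12 genes, 10 had a median of at least 100 counts and a library under 0.1 of it. Genes with a lower median, such as Wdr25, were not counted there. The count was 128 without db/db brazzein replicate 1, 85 and 79 without db/+ brazzein replicate 1 or 2, 43 and 20 without db/+ water replicate 1 or 2, 19 and 36 without db/+ sucrose replicate 1 or 2, and 21 without db/db brazzein replicate 2 or db/db water replicate 1. In brain 0 genes passed this test (1290 at an unadjusted p under 0.05, DESeq2 194).

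Abundant genes listed near 0 were common in liver. The check required a median of at least 100 counts, so genes low in most libraries, such as Acaca, fall outside it. Of 11348 liver genes with a median of at least 100 counts, 215 were at 3 counts or fewer in db/db brazzein replicate 2, 143 in db/+ brazzein replicate 1, 102 in db/db brazzein replicate 1 and 95 in db/+ water replicate 2. The remaining brazzein library, db/+ brazzein replicate 2, had 38, and the other libraries had 4 to 69, so the number did not follow the drink alone. Libraries of the same group shared these genes 0.979 times as often, relative to independent draws, as libraries of that genotype on other drinks. That ratio is scaled by the number of such genes in each library, so it cannot see a difference in number between groups. Within db/db the number was 102 and 215 on brazzein, 14 and 4 on sucrose, and 22 and 28 on water. Within db/+ it was 143 and 38 on brazzein, 69 and 52 on sucrose, and 57 and 95 on water. On water and on sucrose, each db/+ liver thus had more such genes than each db/db liver. A loss of transcript that follows genotype and drink is therefore left open for these genes as a set. It also stays open that estimates for certain genes may fail in single libraries. Libraries that share neither genotype nor drink had 22.6 times as many such genes in common as independent draws give. A first version of this test left out genes near 0 in more than 4 libraries and gave 21.2. The genes called by the interaction test were selected for such values, so a real loss in any of them is left open and untested.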

How the results depend on the processing

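The alternatives that leave out genes listed near 0, 2 liver libraries or 3 brain libraries were chosen after seeing the data, and the cause of a change was not tested unless it is stated. The total of 2937 liver genotype genes stayed within 1.5 times with RLE factors, with no filter, with the replicate block and without the near-0 genes or the 2 libraries. DESeq2 called more in every comparison, 4848 liver genes for genotype over drinks, 2132 on water, 1590 on sucrose and 1912 on brazzein. In db/db liver it called 76 for sucrose against water, 561 for brazzein against water and 1378 for brazzein against sucrose, in db/+ liver 225, 175 and 440, and 381 for the interaction. In brain it called 869 for genotype over drinks, 145 on water, 343 on sucrose and 218 on brazzein. For the same pairs of drinks it called 165, 93 and 111 in db/db brain, 82, 74 and 48 in db/+ brain, and 194 for the interaction. RLE factors gave 0 brain genes for genotype on water and 1 brain list for brazzein against water in db/db. No filter, which adds genes to the adjustment, gave 193 liver genes for genotype on water and 2 for sucrose against water in db/db. In brain it gave 1 each for genotype over drinks, on water and on sucrose, 2 for sucrose against water in db/db, and 1 each for sucrose and for brazzein against water in db/+. Replicate numbers did not pair the samples: over 15 pairs of groups the correlation of same-numbered deviations was -0.165 to 0.0754 in liver and -0.0671 to 0.0514 in brain, with 0 over 0.1. With the replicate block, genotype gave 147 liver genes on water, 72 on sucrose and 194 on brazzein, and in db/db liver 14 for brazzein against water and 20 for brazzein against sucrose. With that block, sucrose against water in db/+ liver gave 0, the liver interaction 5, brain genotype 0 over drinks (Sparc and C4b at an adjusted p of 0.106 each) and 0 on water, and brazzein against sucrose in db/db brain 1. Without the near-0 genes (447 fewer liver genes tested and 59 fewer brain genes), db/db liver gave 2, 13 and 17 for sucrose against water, brazzein against water and brazzein against sucrose, and db/+ liver 0, 0 and 1. The liver interaction then gave 2, and brazzein against sucrose in db/db brain 1. The 2 liver libraries with most near-0 genes were db/+ brazzein replicate 1 and db/db brazzein replicate 2. Leaving them out left 1 brazzein library per genotype. The brazzein counts of that fit therefore assume that a lone library varies like the other groups. Without the 2 liver libraries with most near-0 genes, genotype gave 500 on water and 391 on sucrose, the drinks in the same order 2, 91 and 100 in db/db and 8, 52 and 95 in db/+, the interaction 97, and the lists 6 for brazzein against water and 11 for brazzein against sucrose in db/db. Without the 3 brain libraries, genotype gave 6 over drinks, 4 on sucrose and 2 on brazzein, the drinks 1, 1 and 0 in db/db and 12, 3 and 2 in db/+, the interaction 3, and the brazzein against water lists 1. With an estimated correlation, camera passed 0 liver lists for genotype, 0 for sucrose against water, 0 for brazzein against water and 1 for brazzein against sucrose in db/db, and in brain 0 for genotype, 0 for sucrose against water and 0 for brazzein against water. For genotype in liver, fry passed 15 lists, 14 of them among the 16 that camera passed at the preset correlation. It passed 1 liver list for each pair of drinks in db/db, and in brain 6 for genotype and 0 for sucrose or brazzein against water. Leaving out each library in turn assumes that a lone library varies like the other groups. It gave 1407 to 3402 liver genes for genotype over drinks, 14 to 606 on water, 19 to 438 on sucrose and 131 to 389 on brazzein. The drinks gave 1 to 12, 16 to 200 and 25 to 302 in db/db liver, 0 to 46, 1 to 94 and 4 to 105 in db/+ liver, and 10 to 128 for the interaction. Liver lists ran 14 to 17 for genotype, 9 to 16 for sucrose against water, 1 to 6 for brazzein against water and 2 to 10 for brazzein against sucrose. The shift of genotype genes between brazzein and sucrose ran from -0.27 to 0.25, with the lower set passing camera in 3 of these fits, and 2 settings gave no value because fewer than 20 genes a side were left. In brain the ranges were 1 to 42 for genotype over drinks, 0 to 74 on water, 0 to 19 on sucrose and 0 to 29 on brazzein. The drinks gave 0 to 30, 0 to 22 and 0 to 18 in db/db, 0 to 73, 0 to 73 and 0 to 13 in db/+, and 2 to 26 for the interaction. Brain lists ran 10 to 17 for genotype, 2 to 3 for sucrose against water (without db/db water replicate 2 only cholesterol synthesis was kept of the 2), 0 to 3 for brazzein against water and 0 for brazzein against sucrose. Depth was 58287665 to 79385804 counts per library. The spread between replicates was larger in liver (biological coefficient of variation 0.532, with 0.278 in brain), where fewer simulated changes were recovered. Whether spread or depth set that recovery was not tested.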

Other observations

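The counts of other splits, the tests of the pituitary and cerebellum lists and the list tests in db/+ were chosen only after the results were seen.

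Among the db/+ livers, those on sucrose held other levels of Lepr and Fgf21. Lepr averaged 16.5 ± 3.49 CPM on sucrose against 4.54 ± 2.99 on water and 2.34 ± 0.617 on brazzein (SD, n = 2 each). The hormone gene Fgf21 was at 17.0 ± 4.96 CPM on sucrose, 7.10 ± 4.41 on water and 3.18 ± 1.78 on brazzein. Neither gene passed between drinks in db/+ liver in edgeR. Cholesterol synthesis genes had a median log2 of 1.10 on brazzein against sucrose in db/+ liver, bile acid genes 0.74, macrophage genes -1.04, matrix genes -0.59 and interferon response genes -0.53. Camera passed these lists at the preset correlation, with adjusted p = 0.310 for bile acid genes and 0.395 for the others with an estimated correlation. In brain, db/+ water replicate 1 had the highest Fos (52.0 CPM, others 5.83 to 27.9) and Arc (219 CPM, others 35.1 to 125), both induced by neuronal activity, along with its low Pcp2 (17.3 CPM). Cerebellum markers had a median log2 of 0.49 on sucrose and 0.46 on brazzein against water in db/+ brain (camera adjusted p = 1.67e-10 and 1.02e-10, adjusted p = 0.614 and 0.598 with an estimated correlation).

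Oxidative phosphorylation genes were higher on brazzein than on sucrose in db/db liver (median log2 0.70). The tables argue against 1 library as the source, since the median kept at least 0.938 of its value without any of the 4 libraries. The median of the 42 members with a length (0.71) lay at percentile 100 of 10000 random lists matched on transcript length and level. Those lists already had a median of 0.52, so genes of like length and level went the same way. They were drawn gene by gene, so their spread leaves out variation that the genes of the list share. The lengths came from an annotation of another build than GRCm39. Length and level as the whole cause are therefore left open. Also open is a rise of short abundant transcripts shared with ribosomal protein genes. Their median was 0.875 of the list's (0.877 in a first version limited to genes over 10 CPM). An effect of the drink is open as well, and it was not tested apart from that rise.

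The count of liver genotype genes can be told from chance: of 100 splits that exchange genotype labels within drinks, 1, the real one, gave as many as 2937 genes, and the highest other gave 642. For the 16 liver lists chance is not excluded, since 6 of 100 splits passed as many and the highest other passed 17. For the 2 brain genes chance is not excluded either (22 of 100 splits, highest other 5), nor for the 15 brain lists (5 of 100 splits, highest other 17). The other splits passed a median of 10 liver lists and 6 brain lists. The other splits with as many lists as the real one exchanged 1 or 2 libraries of each genotype. They therefore kept part of the real labels.

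Brain genotype lists included several of non-neural tissue (choroid plexus, ependymal cells, meninges, erythroid cells, hepatocytes and pituitary). Whether pituitary tissue in the 2 libraries high in Gh (311 and 111 CPM) accounts for the pituitary list is left open: of 9 tested members other than Gh and the 4 pituitary genes first seen with it, 2 (0.222) were higher in both than in any other library, which does not decide it. Of the 19 genes of this list, 9 averaged above 1 CPM in brain and 2 are shared with other lists. Less cerebellum in db/+ water replicate 1 may account for the cerebellum list on water, since 16 of 22 members other than Pcp2 and the cerebellum genes first seen with it (0.727) were lower there than in any other library. Unequal dissection of these 3 libraries is left open as a source of the rest. Without them, 1 db/+ library per drink remains and 9 of the 15 lists passed in the same direction, a number between the bounds set for either answer. Of the lists of non-neural tissue, meninges, erythroid cells and hepatocyte markers still passed at the preset correlation. Their median log2 values were 0.19, 0.57 and 1.49 with all libraries and 0.15, 0.50 and 2.97 without the 3. Those differences were thus also seen outside the 3 libraries. Such a pass cannot exclude chance, since other splits of the genotype labels passed a median of 6 brain lists. Choroid plexus (0.10 and 0.03), ependymal cells (0.11 and 0.03) and pituitary (-0.55 and -0.12) no longer passed (adjusted p = 0.466, 0.294 and 0.990). Their medians were nearer 0 and the libraries fewer, and which of these ended the calls was not tested. Of 15 hepatocyte markers, 1 averaged above 1 CPM in brain and 1 is shared with another list, so their difference rests on low counts, and an effect of genotype is left open and untested.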
